A study of Arabidopsis thaliana with 3 samples.

How the data were processed

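Total RNA of wild-type and apetala1 inflorescences was hybridised together on each of 3 two-colour cDNA arrays, per the labels. The deposited table holds 1 log2 ratio per probe and array, preprocessed and normalized by the authors by a published procedure, per the labels. The scanner, background correction, normalization, spot filters, dyes, any dye swap and the direction of the ratio are not given in the sources used here. That the deposited log2 values are on base 2 was read from the values themselves: multiplied by the natural log of 2, 98.7%, 98.4% and 98.6% of those on arrays 1, 2 and 3 were whole multiples of 0.0001, within 0.02 of a step, so they were natural logs written to a fixed number of decimals and then converted. The column medians were 0.0023, 0.023 and 0.0091, so each array had been centred near 0, and any difference common to most transcripts is removed. The direction stays unknown, and is called likely from the channel order alone. All arrays correlated positively, so they run the same way. Of the value columns, 0 were left unmapped.

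Probe identifiers name a plate and a well. No annotation of the probes was used here, so probes could not be joined to loci, and the reference table of gene names could not be applied. The design fixed before the data were examined foresaw averaging the probes of a locus, 19 gene lists (18 of them naming 396 loci, and cytosolic ribosomal proteins by name), the value of AP1, and a test of the ratio's direction on gene lists. None of these could be run, every probe was tested on its own, and the word probe replaces gene throughout. The rule for single probes, also fixed beforehand, was at most 2 identifiers of each sign where no gene names exist: those with the largest mean ratio among probes past the threshold with the same sign on all 3 arrays.

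Ratios were tested as deposited with limma 3.58.1 in R 4.3.3: lmFit with an intercept alone, eBayes with default settings, two-sided, and Benjamini-Hochberg adjustment over 9413 probes at 0.05. No pseudocount, filter or further normalization was applied. The 3 arrays counted as 3 replicates, since the labels list them as separate samples, and averaging the pair with the shared set label was an alternative. With 3 arrays the variance of a probe was shrunk towards a prior SD of 0.27 with 7.68 prior degrees of freedom, and the median half-width of a probe's 95% interval was 0.34 on the log2 scale. A mean ± SD of a probe is over the 3 arrays, and carries no technical replicate of the spot.

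The fit was tested on simulated data with variances drawn from the prior fitted to these arrays and 200 of 9413 probes changed. It recovered 19.5% of probes changed 1.5-fold, 82.5% of those changed 2-fold and 100% of those changed 4-fold. Of 135 calls 5.19% were unchanged probes, and with no changed probe there were 0 calls. The simulated variances came from the prior that the fit itself assumes. The recovered shares and the share of wrong calls therefore hold for data of that model. They do not give the power or the error rate on the real arrays. The real arrays differed in the spread of their ratios, some carried a position pattern, and many probes were near-identical. The search for groups found 93.3% of a planted group of 30 near-identical profiles. This group was planted with ratios close to those of the largest positive group in these data and a spread well within the search distance. The result therefore does not show how large a group the search returns where none was planted.

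Alternatives planned beforehand were centring and scaling of the arrays, leaving out each array, averaging arrays 2 and 3, robust eBayes, a plain one-sample t-test on the log ratios as a comparison of methods, other thresholds, and rank correlation. Alternatives added after seeing the data were centring by position class, centring by plate, leaving out the largest group of near-identical profiles, counting near-identical profiles once, and distances of 0.2 and 0.4 for near-identical profiles. A group of near-identical profiles was made of the probes within 0.3 of one probe on every array, the probe chosen being the one with the most such neighbours. Profiles were counted by complete linkage with all pairs within 0.6 on each array. Position classes were the row and the column of the source well, each taken modulo 4, which gave 16 classes.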

Results

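RNA of whole inflorescences of Arabidopsis thaliana was compared between wild-type plants and plants of the apetala1 mutant on 3 two-colour cDNA arrays. APETALA1 (AP1) encodes a MADS-domain transcription factor that specifies floral meristem identity and the identity of sepals and petals. Its mutants form few or no petals, bear leaf-like organs in place of sepals, and develop secondary flowers in their axils. The comparison therefore asks which transcripts of the inflorescence differ in abundance when AP1 function is lost. On every array wild-type RNA was in channel 1 and apetala1 RNA in channel 2, so each array carries the whole comparison and its log2 ratio was set against 0. Array 1 is labelled as set 1, and arrays 2 and 3 both carry the label set 2. All 3 arrays gave a value for each of 9413 probes, and none was missing. The deposited ratios carry no signal intensities, so the signal behind a probe is unknown, and the precision is limited by the number of arrays.

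The labels do not state the dyes or the direction of the ratio. From the order of the channels a positive ratio is likely a higher level in apetala1 and a negative ratio a higher level in wild type. This direction is called likely only, and results are given by sign. The probes are identified by plate and well, and no table pairing them with genes was used here. The ratio of AP1 itself and of the gene lists fixed beforehand (floral organ identity, petal, stamen, carpel, photosynthesis and others) was therefore not analysed here.

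Between apetala1 and wild type 808 of the 9413 probes, or 8.58%, had a mean log2 ratio different from 0. The test was limma's moderated test with Benjamini-Hochberg adjustment at a threshold of 0.05. Of these, 412 had a positive ratio, likely higher in apetala1, and 396 a negative ratio, likely higher in wild type. All 808 had the same sign on all 3 arrays, but 78 of them were at least 2-fold apart on arrays 1 and 2 and had an absolute log2 ratio under 0.5 on array 3. The median absolute log2 ratio of the 808 was 0.83, and no probe with an absolute mean below 0.51 passed. Over all probes 4299, or 45.7%, had 1 sign on all 3 arrays, where chance gives 25%. Before adjustment 2435 probes had p under 0.05, and a plain one-sample test on the same values called 0 probes after adjustment and 1248 before. Leaving out array 1 gave 466 probes, of which 169 were positive, and leaving out array 3 gave 2117. These fits also estimated the spread anew: the prior degrees of freedom were 7.68 with all arrays, 42.0 without array 1 and without limit, that is 1 spread for all probes, without array 3. The arrays and the estimate of the spread thus changed together. Averaging arrays 2 and 3 into 1 replicate, as their shared set label would allow, gave 2046, with a prior SD of 0.20 in place of 0.27. This fit had 2 values per probe and 14.5 prior degrees of freedom. It too estimated the spread anew, so its higher count is no sign of stronger evidence. Nothing in the labels says that the 3 samples came from separate plants or pools, so the p-values measure the spread between these arrays, which may be technical. Apetala1 was in channel 2 on every array, and the dyes and any dye swap are unknown. A dye effect of single probes that repeats on all arrays can therefore not be told apart from a genotype difference. It would also raise the share of probes with 1 sign on all arrays.

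**Figure D1:**
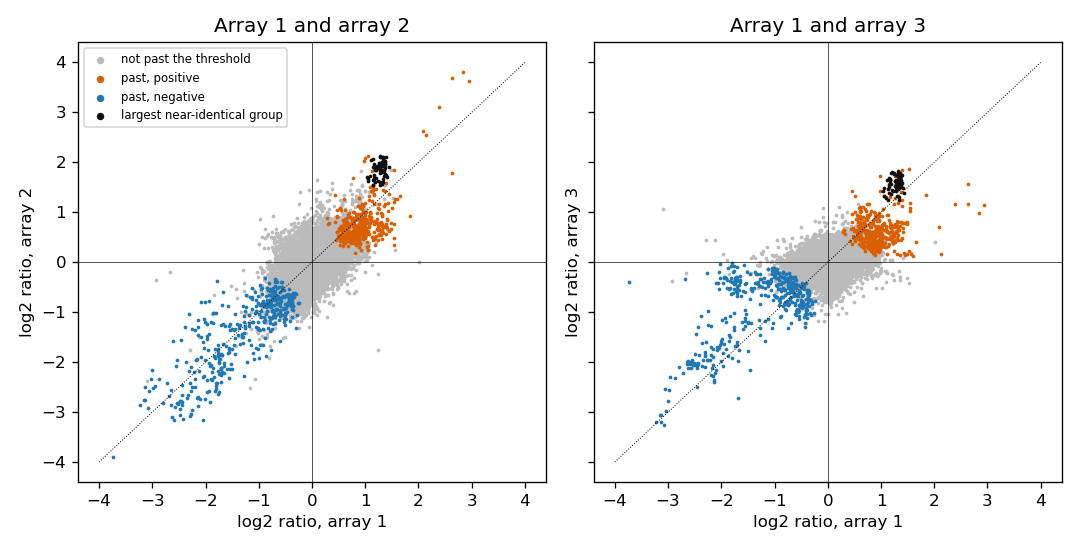
Each point is a probe, with its log2 ratio on array 1 on the horizontal axis and on array 2 (left) or array 3 (right) on the vertical axis. Orange and blue points passed the threshold with a positive or negative mean, black points are 71 probes with nearly the same ratios, grey points did not pass, and the dotted line marks equal ratios. Arrays 1 and 2 lie along the line (r = 0.74), while on array 3 part of the negative probes lies near 0.

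In the mean over the 3 arrays, the largest differences were on the negative side, that of the transcripts that were likely more abundant in wild type. With the same sign required on every array, 197 probes were at least 2-fold apart with a negative ratio and 109 with a positive ratio. At 3-fold the counts were 91 and 44, and at 4-fold 55 and 4. At 6-fold 11 negative probes and 0 positive probes remained. On array 3 the highest log2 ratio was 1.86 and the lowest -3.26. The highest was 2.94 on array 1 and 3.81 on array 2, and the lowest -3.74 and -3.91. The excess at 4-fold and above may thus depend on array 3, and it was not recounted without that array. At 1.5-fold the sides were nearly equal, with 409 negative and 419 positive probes. Of the probes at least 2-fold apart, 195 of the 197 negative and all 109 positive ones passed limma's test. Of the 109 positive probes, 71 had nearly the same ratios, as described below. Part of the fall in the positive counts may thus reflect 1 profile, and the counts at 3-fold and above were not repeated without it. The excess of negative probes at 2-fold held when any 1 array was left out, with 185 negative against 100 positive probes without array 1, 162 against 120 without array 2 and 263 against 190 without array 3. On array 1 alone 248 probes were at least 2-fold apart with a negative and 233 with a positive ratio. These counts were 330 and 212 on array 2, and 136 and 117 on array 3. Among single arrays the excess was thus marked on array 2 only, and the means without 1 array share arrays. The excess was counted and not tested.

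**Figure D2:**
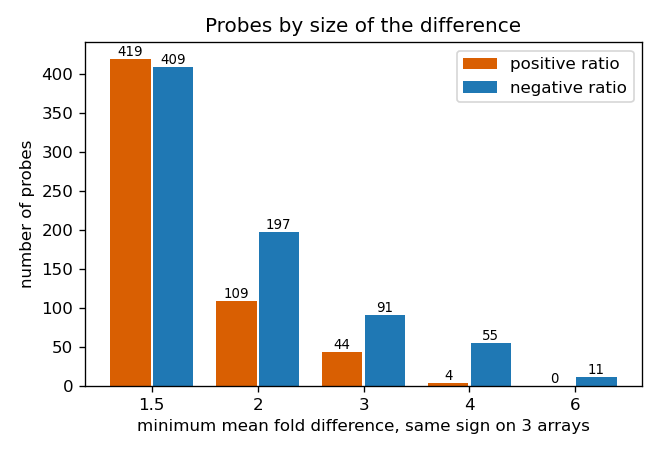
Bars give the number of probes (vertical axis, from 0) whose mean ratio reached the fold difference on the horizontal axis with the same sign on all 3 arrays. Orange bars are positive ratios and blue bars negative ratios: the sides are close at 1.5-fold (419 and 409) and far apart at 4-fold (4 and 55).

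The strongest negative probe, GP070F5 (plate 070, well F5), had a mean log2 ratio of -3.10 ± 0.20 (SD, n = 3), an 8.55-fold difference, with an adjusted p of 6.98e-06 in limma's test. Probe GP086D1 followed with -3.09 ± 0.17 (SD, n = 3) and the same adjusted p. On single arrays GP070F5 ranged from -3.23 to -2.87 and GP086D1 from -3.26 to -2.93, so for both the mean exceeded the SD over the arrays by more than 10 times. On the positive side GP042G5 had 2.57 ± 1.28 (SD, n = 3), a 5.96-fold difference, with an adjusted p of 0.00184. GP033D10 had 2.55 ± 1.43 (SD, n = 3) with an adjusted p of 0.00402. These 2 probes were less even. GP042G5 read 2.94, 3.63 and 1.15 on arrays 1, 2 and 3, and GP033D10 read 2.84, 3.81 and 0.995. With limma's robust variance estimate their adjusted p rose to 0.0561 and 0.0732, so both calls were lost, with the fold unchanged. Over their 10 alternatives each, the adjusted p of GP042G5 ran from 7.56e-57 to 0.0561 and that of GP033D10 from 3.86e-58 to 0.0732, the lowest coming from limma without array 3 and 1 spread for all probes.

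Many of the positive probes at least 2-fold apart had nearly the same ratios. Of the 109 positive probes at least 2-fold apart, 71, or 65.1%, lay within 0.3 of one probe's log2 ratio on each of the 3 arrays. Their means were 1.27 ± 0.09 on array 1, 1.85 ± 0.16 on array 2 and 1.57 ± 0.14 on array 3 (SD over 71 probes). They came from 47 plates, with at most 3 from any plate. On the negative side the largest such group held 31 of 197 probes, or 15.7%, with means of -1.74, -2.05 and -0.34 on arrays 1, 2 and 3. Probes grouped so that every pair lay within 0.6 on each array formed 14 profiles on the positive side and 34 on the negative side. Counts of probes are therefore not counts of distinct expression profiles, and without the group of 71 the count of positive probes at least 2-fold apart was 38. The size of the group depends on the distance allowed: within 0.2 it held 45 probes, or 41.3%, which leaves 64, and within 0.4 it held 80, or 73.4%, which leaves 29.

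The arrays agreed to different degrees. Across probes, which are not independent replicates, Pearson's r was 0.74 between arrays 1 and 2, 0.64 between arrays 1 and 3 and 0.50 between arrays 2 and 3. Spearman's rho was 0.60, 0.50 and 0.27. The pair that shares a set label was thus the least alike, and at most 3 of the 9413 values were identical between any 2 arrays, so no array was a copy of another. This does not show that the arrays carried separate RNA. Array 3 had the narrowest ratios, with an SD of 0.38 over probes against 0.52 on array 1 and 0.57 on array 2. Of the 332 probes at least 2-fold apart in 1 direction on both arrays 1 and 2, 104, or 31.3%, had an absolute log2 ratio under 0.5 on array 3. Of these, 80 were negative on arrays 1 and 2 and 24 positive. By the same rule 0 of 197 probes were that low on array 1 alone, and 5 of 204 on array 2 alone. With all arrays scaled to 1 median absolute deviation the counts were 44 of 266, or 16.5%, on array 3, 13 of 214, or 6.07%, on array 2 and 2 of 193 on array 1. The 80 negative probes had mean log2 ratios of -1.58 ± 0.44 on array 1, -1.86 ± 0.54 on array 2 and -0.20 ± 0.21 on array 3 (SD over probes).

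Ratios on arrays 2 and 3 varied with the position of the source well, a pattern looked for after the data were seen. The wells were divided into 16 classes by row and column position, each repeating every 4 rows and 4 columns of the 96-well plate. Median log2 ratios of the classes ran from -0.10 to 0.18 on array 2 and from -0.13 to 0.13 on array 3. On both arrays their spread was larger than in any of 1000 shuffles of wells within plates, with a one-sided permutation p of 0.001, the smallest these shuffles can give. On array 1 the medians ran from -0.03 to 0.04, with a permutation p of 0.124. The class medians of arrays 2 and 3 were opposed, with r = -0.92 (two-sided permutation p = 1e-05, the smallest possible; 3e-05 adjusted over 3 pairs) and rho = -0.91 (permutation p = 1e-05; 3e-05 adjusted). Without the 2 classes farthest from the median of array 2, r was -0.90. The other pairs gave r of 0.01 (permutation p = 0.96) and -0.14 (permutation p = 0.61). The classes accounted for 2.58% of the variance on array 2 and 3.16% on array 3 (adjusted R squared). Centring each array by class, an alternative chosen after seeing the data, raised r between arrays 2 and 3 to 0.54 and the number of probes past limma's threshold to 1007, among them all 808 called before.

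**Figure D3:**
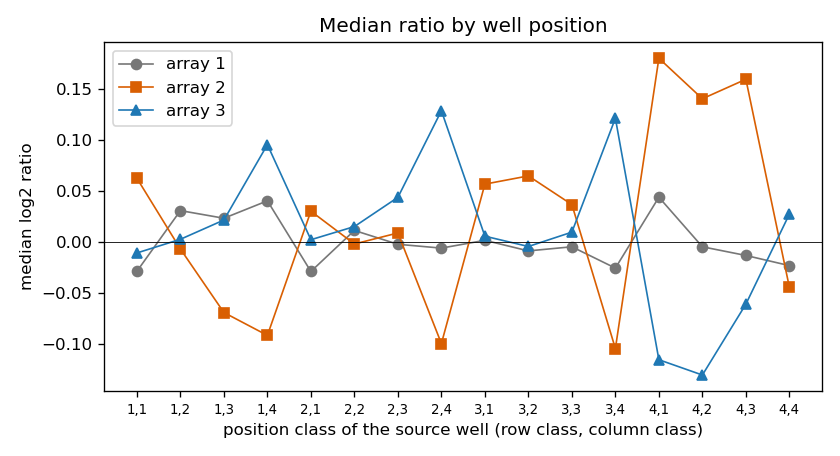
Median log2 ratio (vertical axis) of the probes in each of 16 well position classes (horizontal axis, row class and column class, each repeating every 4 wells) on array 1 (grey), array 2 (orange) and array 3 (blue). Arrays 2 and 3 move in opposite directions between -0.13 and 0.18, and array 1 stays between -0.03 and 0.04.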

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

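Centring by plate or position class, leaving out the largest group, counting profiles once and the distances of 0.2 and 0.4 were chosen after seeing the data. The number of probes past the threshold was 808 (412 positive, 396 negative), and centring, scaling, robust eBayes, a 1.5-fold minimum, centring by plate or by position class and leaving out the largest group of near-identical profiles gave totals of 679 to 1007, each within 1.5 times. Leaving out 1 array gave 466 (without array 1) to 2117 (without array 3) in total, 169 to 1023 positive and 264 to 1094 negative. These fits estimated the spread anew, and the one without array 3 assumed 1 spread for all probes. Averaging arrays 2 and 3 gave 2046 (1050 positive, 996 negative), an adjusted p under 0.01 gave 326 (158 and 168), and the plain t-test gave 0 in total and on each side, with a smallest adjusted p of 0.0737 on 2 degrees of freedom. At a minimum of 1.5-fold 419 positive and 409 negative probes were counted, and at 3-fold 44 and 91, by construction. The 2-fold counts ranged over the arrays left out from 100 to 190 positive, the highest without array 3, and from 162 to 263 negative. Without the largest group 38 positive probes were at least 2-fold apart, and with near-identical profiles counted once 14 positive and 34 negative, against 109 and 197. With a distance of 0.2 in place of 0.3 the profiles were 18 and 56 and the largest positive group 45 probes, and with 0.4 they were 9 and 22 and the group 80. Between arrays 1 and 2, 1 and 3, and 2 and 3, Spearman's rho was 0.60, 0.50 and 0.27, Pearson's r without the tenth of probes with the largest absolute mean 0.47, 0.37 and 0.0713, and r after centring by position class 0.75, 0.65 and 0.54. Leaving out probes by their mean lowers r by construction. The 4 named probes kept their direction in all 40 refits and passed in 38, the exceptions being GP042G5 and GP033D10 under robust eBayes. The plain t-test was not among these 40, and it called 0 probes, so none of the 4 passed it. Each ratio already pairs both genotypes within an array, so no other pairing was fitted. Not run for want of probe annotation were the gene lists, AP1, the averaging of probes per locus and the removal of close gene families. Every probe had a value on all arrays, so a minimum of 2 arrays changed nothing.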

Other observations

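The tests of plates, neighbouring wells, near-identical profiles, well positions and probes low on array 3 were chosen after these patterns were seen, and only the sign patterns of the arrays were planned. The probes came from 114 plates numbered from 0 to 147, and calls were unevenly spread over them. The plates were divided at numbers set after a lower spread of the ratios above plate 120 had been seen, so the p-values of this division are too small. On plates 120 to 147, 125 of 2259 probes, or 5.53%, passed limma's threshold (exact binomial 95% interval 4.63 to 6.56, for counting error only), against 193 of 1925 on plates 0 to 59, 247 of 2663 on plates 60 to 89 and 243 of 2566 on plates 90 to 119. Outside the group of 71 near-identical positive probes the shares were 5.53% on plates 120 to 147 and 8.64% on the plates before them (Fisher's exact test, two-sided, p = 9.61e-07, treating probes as independent, which near-identical probes are not). On these last 28 plates the SD of the log2 ratios over probes was 0.42, 0.42 and 0.25 on arrays 1, 2 and 3, against 0.54, 0.61 and 0.42 on plates 90 to 119. With 2259 of the 9413 probes, the last 28 plates held 15 of the 197 negative and 8 of the 38 remaining positive probes at least 2-fold apart. The negative ones were thus well below the share of probes there, and the remaining positive ones close to it. What the clones of these plates are was not analysed here.

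Among single plates, each set against all others, 3 of 114 had a higher share of calls and 0 a lower one at an adjusted p under 0.05 (Fisher's exact test, two-sided, Benjamini-Hochberg over 114 plates, treating probes as independent). Plate 005 had 15 calls among 59 probes (25.4%, adjusted exact p = 0.0111), plate 002 had 14 among 61 (23.0%, adjusted exact p = 0.0297) and plate 001 had 15 among 71 (21.1%, adjusted exact p = 0.0322). All 15 calls on plate 001 were negative, against 4 of 14 on plate 002 and 11 of 15 on plate 005. Plate 011, with 15 of 76, did not pass (adjusted exact p = 0.0803). On the 3 plates the mean log2 ratios of neighbours in a row correlated at 0.47 over 141 pairs of wells and those of neighbours in a column at 0.12 over 116 pairs, against 0.04 and 0.03 on the other 111 plates. Such likeness was not particular to the 3 plates. Plate 004, among the other 111, had the highest r in a row of any plate, 0.66, with 7 of 56 probes called. Plate 070, also among them, had 0.34, as did plate 001 of the 3. Of 17 pairs of neighbours in a row on the 3 plates that both passed the threshold, 13 lay within 0.3 of each other on every array, against 14 of 70 on the other plates. Calls on the 3 plates are therefore not independent of each other, and the p-values of the plates are too small. The other 111 plates held 764 of the 808 calls.

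The 71 positive probes with nearly the same ratio on every array were absent from plates 120 to 147, where 17.0 were expected from the number of probes (Fisher's exact test, two-sided, p = 4.25e-09, for the same division of plates). That test treats the 71 as independent, which near-identical probes are not, so its p is too small for this reason as well. Carry-over between neighbouring wells is argued against, because 0 of the 71 lay beside, or in the same well of the plate before or after, another member. Random sets of as many probes had 2.66 such members on average and at most 16, over 1000 sets. Carry-over between wells farther apart, such as those of 1 position class, was not tested. A first form of the test of neighbouring wells also asked how many plates held the group, 47 against a mean of 52.9 for random sets. That form left the matter undecided, and was replaced after that was seen. A ceiling of the measured ratio is argued against on arrays 1 and 2, where 6 probes lay above every member on both, and stays open on array 3, where 2 probes did. A candidate explanation is that several probes report one transcript or close copies of it, since the group held 65.1% of the positive probes at least 2-fold apart (41.3% with a distance of 0.2), but without probe identities this cannot be told apart from many genes that change together. How large a group chance would give is not known, since a shuffling tried for this was dropped because the group itself made up most of the probes shuffled.

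The opposite position patterns of arrays 2 and 3 repeated between the 6 tiles of 16 wells that make up a plate, with a mean correlation between tiles of 0.759 on array 2 and 0.798 on array 3, against 0.0449 on array 1. That is consistent with an effect of printing position, such as the pin that laid the spot, left in the ratios of arrays 2 and 3 after the authors' normalization. Opposite dyes on arrays 2 and 3, with ratios later turned the same way, could give one position-dependent dye bias opposite signs. Plate medians left after centring by class correlated at 0.0742 between arrays 2 and 3. The other pairs gave 0.307 for arrays 1 and 2 and 0.605 for arrays 1 and 3. The low value for arrays 2 and 3 neither shows nor excludes such a bias, since plates also share real differences. No biological explanation was tested, and with the pattern removed arrays 2 and 3 were still the least alike pair, at r = 0.54.

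The 104 probes changed on arrays 1 and 2 and near 0 on array 3 are not explained as a whole by a narrower scale of array 3, because 41.9% of the 332 probes at least 2-fold apart on arrays 1 and 2 reached 0.8 or more of their mean on array 3, while 32.2% stayed at 0.3 or below. The 332 include the 71 near-identical positive probes, with means of 1.27, 1.85 and 1.57 on arrays 1, 2 and 3. The group's mean on array 3 lay between those on arrays 1 and 2, so part of the 41.9% was this 1 profile. The share without this group was not computed. Scaling all arrays to 1 median absolute deviation left 44 of 266 probes, or 16.5%, low on array 3 alone. The counts were 2 of 193 on array 1 and 13 of 214 on array 2, so a scale difference may account for part of the 104. The position pattern is argued against as the whole cause by its size, since class medians ran only from -0.10 to 0.18 on array 2 and from -0.13 to 0.13 on array 3. After centring by class 94 of these 104 probes, or 90.4%, still met the same rule. Shifts this small could change few of them, so that count adds little. The 104 probes lay on 69 plates and formed 15 profiles. A difference in the plants or flower stages behind array 3, or a dye effect of single probes, stays open and untested.

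Reversing the sign of 1 array at a time gives, with the real one, 4 sign patterns of the 3 arrays. The real pattern gave 808 calls by limma and the highest of the others 0, so 1 of the 4 gave as many, and 4 patterns are too few for a share under 0.05.

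Of the values 27.7%, 27.1% and 29.9% on arrays 1, 2 and 3 were natural logs of 3 decimals rather than 4, where 10% would be by chance. On 1322 probes this held on all 3 arrays, where 212 were expected if the arrays were independent.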
